A study of Mus musculus with 24 samples.

How the data were processed

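RNA of mouse intestinal organoids and intestine was measured on 24 one-colour Affymetrix arrays, 4 in each of 6 groups. Per the labels' protocols, total RNA was extracted with Trizol, 1 µg was labelled with biotin, and organoids were cultured in ENR medium, which holds EGF, Noggin and R-spondin. The deposited values are log2 signals that the authors made with Affymetrix Expression Console and RMA, which corrects background, quantile normalizes between arrays and summarises probes. The versions, the genome build and which arrays were normalized together are not given in the sources used here. The number of arrays limits the precision of every value.

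The deposited table held 72688 probe sets, of which 6732 were controls and 65956 transcript clusters. A symbol was listed for 32750 clusters, and 31258 of these named 1 gene, while 1492 named several and were left out. For 1152 clusters an older symbol was updated. Where a gene had over 1 cluster (441 genes), the one with the highest mean over all arrays was used, which gave 30702 genes. The 33206 clusters without a symbol were left out of the comparisons. Ass1 and Muc2 of the fixed panel had no cluster naming them alone. Positive and negative control probe sets gave each array's area under the curve.

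All 24 arrays were fitted in 1 model of group means with limma 3.58.1 in R 4.3.3, with 18 residual and 4.25 prior degrees of freedom. Each of 8 comparisons was tested per gene with limma's moderated two-sided test and Benjamini-Hochberg adjustment over all genes of the comparison. A gene was called at an adjusted p under 0.05, and a second count asked for at least a 2-fold change. The comparisons were day 30 minus day 3 in fetal and in adult organoids, the difference between these changes, adult minus fetal organoids at day 3 and at day 30, adult minus P0 tissue, and day 3 organoids minus tissue in adult and in fetal or newborn samples. The comparisons, the alternatives, the 30 gene lists and the rule for named genes were fixed before the data were examined.

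The 30 lists of cell type and pathway genes were tested with limma's camera, a competitive test, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 30 lists of a comparison. A list is described where its camera adjusted p is under 0.05 or where it is the suckling enterocyte, adult enterocyte, Paneth cell or stem cell and Wnt target list. Named genes are a fixed panel of 14, the 6 largest rises and 6 largest falls of each comparison among called genes whose groups overlap in no array (for the difference of culture changes, the largest called), and per list up to 4 of the largest called members and the called members that go against their list. Predicted genes with provisional names and joined names were left out. The text prints part of the genes the rule names. Genes of stomach, sex-linked genes and Lgals1 as a marker were chosen after their values were seen.

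The tissue maturation score of an array is the mean log2 level of genes called at least 2-fold higher in adult than in P0 tissue minus that of genes called at least 2-fold higher in P0 tissue. Its differences between organoid groups were tested by exact two-sided permutation of the arrays, adjusted over 4 comparisons. The difference between culture changes was set against permutations of days within each age, which test for no change in either age. Changes in organoids and tissue were compared across genes by Pearson and Spearman correlation and by counts of genes called in both. Other splits of the arrays were counted in full, 35 per pair of groups, and 100 were drawn for the difference of culture changes.

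On simulated data, 100 genes of the fetal culture comparison were shifted by 1, 100 others by 0.5 and the lipid absorption list by 0.5 in the same run. There limma recovered 89 and 54 of 100 and called 13 of 30482 genes left as they were, 8.12% of all calls of the run.

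Alternatives changed 1 choice at a time. They were the mean of all clusters of a gene, genes left out unless above the array median on at least 4 arrays (16966 kept), a trended and robust prior, a fit of the compared groups alone, arrays centred on their median, a second quantile normalization, a replicate block, array weights, an adjusted p under 0.01, an estimated correlation, and each array left out in turn. For the score they were tissue genes with at least a 4-fold change, tissue genes above the organoid median, no genes of non-epithelial lists, and the median over genes. After the data were seen, 3 were added: without fetal day 3 arrays 2 and 3, without P0 arrays 1 and 4, and without P0 arrays 2 and 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation, permutation and figures.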

Results

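The 24 single-colour arrays of mouse RNA formed 6 groups of 4. The groups were organoids grown from fetal intestine of stage E19 or from adult intestine, each after 3 and 30 days of culture, and whole intestine at P0, the day of birth, and from adults. Organoids are epithelial cultures that form crypt-like and villus-like parts. The median of each array lay between 4.18 and 4.43 on the log2 scale. The area under the curve that parts positive from negative control probe sets lay between 0.865 and 0.922. Fetal day 3 replicate 1 had a mean background probe level of 4.04, against 3.43 to 3.63 on the other fetal day 3 arrays. The first principal component of the 30702 genes held 42.5% of the variance and the second 22%. The labels do not say whether replicates are separate animals or cultures, so the tests measure the spread between these arrays, which can be technical, and the number of arrays limits the precision. Values in parentheses are log2 differences of group means (n = 4) ± SE and limma's adjusted p, with spread pooled over all 24 arrays. The median of the negative control probe sets lay between 3.84 and 4.61, and a difference is a lower bound where 1 group's mean lies below that of its arrays. Of the named genes, this holds for Nox4, Tfec, Try4, Jchain, Cubn, Gkn2, Lum, Prss2, Ogn, Mup20, Fut2, Cyp2r1, Cyp3a25, Reg3a, Reg3g, Rgs13, Xist, Cel, Uty, Kdm5d and Igkv4-59, each in at least 1 comparison. The culture change of fetal organoids, its difference from that of adult organoids, and the comparisons of fetal day 3 organoids with adult organoids and with P0 tissue share the same 4 fetal day 3 arrays and are not independent of one another.

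Adult and P0 intestine were compared first, to see how the tissue differs between birth and adulthood. Sis, the sucrase and isomaltase of the adult brush border, was higher in adult tissue (6.81 ± 0.33, adjusted p = 2.4e-13). So were Treh, which encodes trehalase (5.32 ± 0.3, adjusted p = 3.1e-12), and Arg2, which encodes arginase 2 (5.23 ± 0.34, adjusted p = 2.9e-11). Lower in adult tissue were Fcgrt, the receptor that takes up milk IgG (-3.25 ± 0.26, adjusted p = 1.3e-09), Nox4 (-3 ± 0.15, adjusted p = 5.6e-13) and Prdm1, the gene of the transcription factor Blimp-1 (-1.51 ± 0.24, adjusted p = 3.8e-05). Lct, which encodes lactase, averaged 11.72 in P0 and 11.71 in adult tissue and was not called (-0.02 ± 0.39, adjusted p = 0.98). The Paneth cell genes Lyz1 (6.28 ± 0.32, adjusted p = 6.1e-13) and Mmp7 (4.06 ± 0.36, adjusted p = 7.4e-09) were higher in adult tissue. Mki67, a gene of dividing cells, was also higher (0.64 ± 0.21, adjusted p = 0.028), while the stem cell gene Lgr5 (0.8 ± 0.39, adjusted p = 0.14) and the enteroendocrine gene Chga (0.13 ± 0.31, adjusted p = 0.78) were not called. The call of Mki67 ended without P0 replicate 1, 3 or 4 or adult tissue replicate 1, 2 or 3 (0.51 to 0.62, adjusted p from 0.053 to 0.095) and with centred arrays (0.56, adjusted p = 0.095).

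Gene lists are given as the measured members that passed limma's test in each direction and as a camera test of the list. Where a camera call at an adjusted p under 0.05 has no second p beside it, it held with an estimated correlation. Of the suckling enterocyte list, 8 of 11 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 4.3e-10). Dab2, an adaptor of protein uptake, was lowest (-3.81 ± 0.22, adjusted p = 4.8e-12). Of the lysosome and protein endocytosis list, 14 of 16 were lower and 0 higher (14 and 0 adjusted over the list alone, camera adjusted p = 2.9e-18). The protease gene Ctsl was among them (-3.41 ± 0.21, adjusted p = 1.6e-11). Of the adult enterocyte list, 8 of 11 were higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 1.2e-05), the exception being Fbp1, an enzyme of glucose synthesis (-2.52 ± 0.29, adjusted p = 4.7e-07). Of the oncofetal and imprinted growth list, 9 of 12 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 3.3e-13). Plagl1 (-4.54 ± 0.14, adjusted p = 1.2e-16) and Peg3 (-3.42 ± 0.23, adjusted p = 8.4e-11) were lowest. Of the fatty acid oxidation and ketogenesis list, 9 of 13 were lower and 0 higher (9 and 1 adjusted over the list alone, camera adjusted p = 7.3e-08).

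Every measured Paneth cell gene was higher in adult tissue: 11 of 11 were higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 4.7e-14). Itln1 (6.53 ± 0.36, adjusted p = 1.7e-12) differed most. Of the microbe response and mucosal defence list, 13 of 16 were higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 3.1e-08). Reg3g (5.79 ± 0.59, adjusted p = 5.8e-08) and Reg3a (5.73 ± 0.32, adjusted p = 2.1e-12) were among them. Of the leukocyte list, 14 of 15 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 5.6e-15). The plasma cell gene Jchain was higher (6.19 ± 0.2, adjusted p = 3.4e-16), while the macrophage gene Csf1r was lower (-0.48 ± 0.13, adjusted p = 0.01; -0.3 without adult tissue replicate 1). Of MHC class II presentation, 6 of 6 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 1.2e-08). Of MHC class I presentation, 10 of 10 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.2e-08). Genes of other tissue layers were lower in adult tissue. Of mesenchyme and smooth muscle, 12 of 14 were lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 5.7e-12). Of endothelium, 8 of 9 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 8.4e-13). Of enteric neuron and glia, 5 of 8 were lower and 0 higher (5 and 0 adjusted over the list alone, camera adjusted p = 9.8e-06).

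In the goblet cell list, 10 of 13 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 2.1e-05, adjusted p = 0.11 with an estimated correlation). Zg16 (4.56 ± 0.35, adjusted p = 7.1e-10) differed most. In the tuft cell list, 6 of 10 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.53 with an estimated correlation). Rgs13 was among them (2.02 ± 0.44, adjusted p = 0.0012). Of the stem cell and Wnt target list, 3 of 16 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.37). Olfm4 was highest (2.5 ± 0.26, adjusted p = 8.8e-08) and Nkd1, an inhibitor of Wnt signalling, lower (-0.62 ± 0.1, adjusted p = 2.9e-05). Of bile acid and xenobiotic handling, 13 of 24 were higher and 4 lower (15 and 4 adjusted over the list alone, camera adjusted p = 6e-05, adjusted p = 0.16 with an estimated correlation). Cyp3a25, of drug oxidation, was higher (6.4 ± 0.46, adjusted p = 1.8e-10), while the bile acid receptor gene Nr1h4 (-1.36 ± 0.23, adjusted p = 6.1e-05) was among those lower. Of lipid absorption, 9 of 20 were lower and 4 higher (9 and 5 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.53 with an estimated correlation). Cd36 was lowest (-2.09 ± 0.38, adjusted p = 2e-04) and the sterol transporter gene Npc1l1 highest (0.94 ± 0.19, adjusted p = 0.00067). Of arginine and proline synthesis, 3 of 6 were lower and 2 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.28 with an estimated correlation). Asl was lowest (-1.28 ± 0.09, adjusted p = 1.2e-10) and Otc (1.69 ± 0.2, adjusted p = 7.3e-07) and Prodh (0.47 ± 0.12, adjusted p = 0.0057) higher.

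The other 11 lists had camera adjusted p from 0.12 to 0.88. In the sugar uptake and erythroid lists the median and mean differed in sign.

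With limma, 4598 genes were called higher and 3733 lower in adult tissue at an adjusted p under 0.05, 798 and 766 of them with at least a 2-fold change, among them the immunoglobulin gene Igkv4-59 (7.02 ± 0.26, adjusted p = 1.8e-15). The median difference of all genes was 0.082, and the share of called genes that were higher was 55.2%, or 40.2% with arrays centred on their median and 43.1% after a repeated quantile normalization. Without P0 arrays 2 and 3, which carried no Xist signal (3.81 and 4.01, against 10.6 and 10.53 on P0 arrays 1 and 4 and 3.77 to 4.24 in adult tissue), 2480 genes were called higher, and Csf1r (-0.36, adjusted p = 0.17) and Prodh (0.29, adjusted p = 0.17) were not called. P0 intestine is not the same age as the E19 intestine from which the fetal organoids came.

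Fetal organoids at day 30 were compared with day 3, to see whether fetal epithelium changes in culture. Sis rose most, from 6.69 ± 1.15 to 11.45 ± 0.16 (mean ± SD of the log2 level, n = 4), a difference of 4.76 (SE 0.33, adjusted p = 3e-09). Arg2 (3.01 ± 0.34, adjusted p = 1.5e-06) and Treh (2.41 ± 0.3, adjusted p = 6.2e-06) rose as well, and Fcgrt (-1.81 ± 0.26, adjusted p = 3.8e-05) and Prdm1 (-0.92 ± 0.24, adjusted p = 0.01) fell. The Paneth cell gene Lyz1 (1.41 ± 0.32, adjusted p = 0.0038) and the stem cell gene Lgr5 (2.21 ± 0.39, adjusted p = 4e-04) rose. Chga rose by less (0.97 ± 0.31, adjusted p = 0.035). Nox4 was called lower (-0.48 ± 0.15, adjusted p = 0.035), but its means of 3.25 and 2.77 both lay below the negative control medians, so no change is read from it. Mmp7 (0.61 ± 0.36, adjusted p = 0.29), Lct (0.24 ± 0.39, adjusted p = 0.74) and Mki67 (0.2 ± 0.21, adjusted p = 0.59) were not called. The call of Chga ended without fetal day 3 replicate 2 or 3 or fetal day 30 replicate 1 or 3 (0.78 to 0.94, adjusted p from 0.078 to 0.13).

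**Figure D1:**
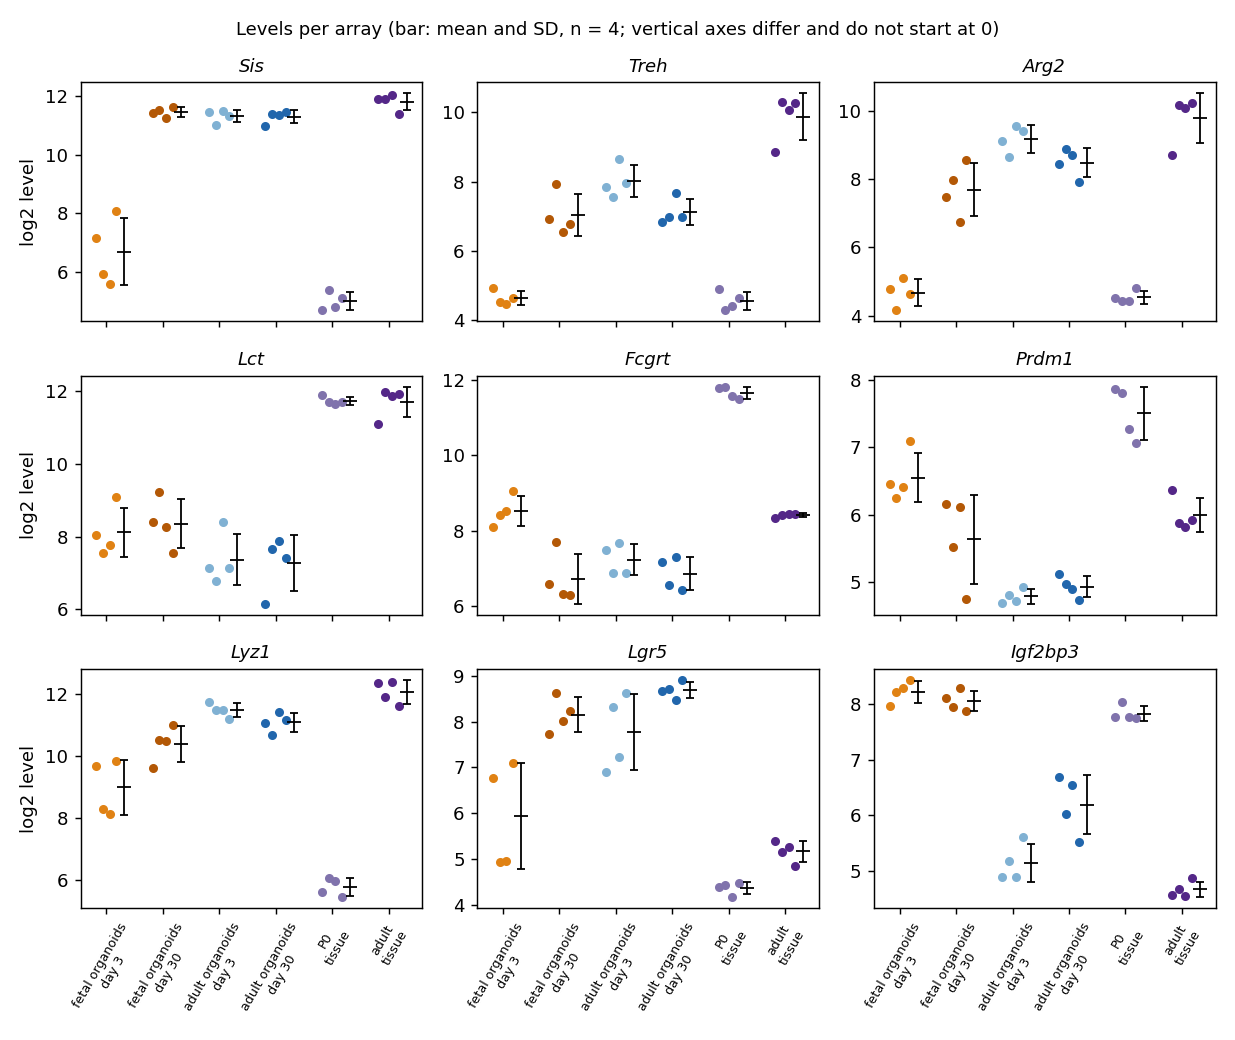
Log2 level of 9 genes on each of the 24 arrays, by group, with the mean and SD of each group (n = 4) as a bar beside the points; the vertical axes differ between genes and do not start at 0. Sis averaged 6.69 in fetal organoids at day 3 and 11.45 at day 30, against 11.32 and 11.3 in adult organoids.

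Of the adult enterocyte list, 8 of 11 rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 4.1e-08), where the fructose enzyme gene Khk followed Sis, Arg2 and Treh (2.36 ± 0.17, adjusted p = 3e-09) and Fut2, which encodes a fucosyltransferase, fell (-1.77 ± 0.45, adjusted p = 0.0082). Among suckling enterocyte genes, 8 of 11 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 7.6e-07, adjusted p = 0.069 with an estimated correlation). Dab2 was lowest (-2.22 ± 0.22, adjusted p = 2.9e-07). Of the lysosome and protein endocytosis list, 14 of 16 fell and 0 rose (15 and 0 adjusted over the list alone, camera adjusted p = 2.4e-13). Ctsl was among them (-2.04 ± 0.21, adjusted p = 5.2e-07). Of the stem cell and Wnt target list, 11 of 16 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.2e-09), with Smoc2 (2.36 ± 0.29, adjusted p = 4.2e-06) and Olfm4 (1.58 ± 0.26, adjusted p = 0.00017) beside Lgr5. Of the oncofetal and imprinted growth list, 7 of 12 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 3.4e-08). Grb10 was lowest (-2.05 ± 0.13, adjusted p = 7.5e-10). Of the Paneth cell list, 7 of 11 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.7e-07, adjusted p = 0.13 with an estimated correlation). Defa21 (3.06 ± 0.45, adjusted p = 4.4e-05) differed most. Of sugar uptake and fructose metabolism, 6 of 9 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 2.8e-08, adjusted p = 0.072 with an estimated correlation). Fbp1 was among them (1.9 ± 0.29, adjusted p = 8.7e-05). Of fetal spheroid and regenerative epithelium, 11 of 13 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 3.1e-09, adjusted p = 0.072 with an estimated correlation). Il1rn (-2.83 ± 0.52, adjusted p = 0.00048) and Anxa1 (-2.63 ± 0.42, adjusted p = 0.00013) were lowest.

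Genes of cell types outside the epithelium fell on the same arrays. Of mesenchyme and smooth muscle, 12 of 14 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.069 with an estimated correlation). Dcn (-2.53 ± 0.66, adjusted p = 0.0095) led the list. Of endothelium, 5 of 9 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.00036, adjusted p = 0.13 with an estimated correlation). Cdh5 (-1.29 ± 0.17, adjusted p = 1.1e-05) differed most. Of the leukocyte list, 4 of 15 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.19 with an estimated correlation). Itgam (-1.38 ± 0.23, adjusted p = 0.00015) led the list. Of the pancreatic acinar cell list, 8 of 11 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 2e-04, adjusted p = 0.27 with an estimated correlation), with the trypsinogen gene Try4 among them (-3.25 ± 0.65, adjusted p = 0.0012) and Clps, which encodes colipase, rising (1.1 ± 0.21, adjusted p = 0.00061). Among 8 stomach genes chosen after the values were seen, 6 fell (median -3.29), and among 19 others 7 fell and 1 rose (median -0.23). With day 3 arrays 2 and 3 left out, 4 of the 8 (median -1.47) and 2 of the 19 fell. Of bile acid and xenobiotic handling, 6 of 24 rose and 2 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.4 with an estimated correlation). Cyp3a11 rose (4.34 ± 0.32, adjusted p = 5.7e-09), and Slc51a (-1.08 ± 0.22, adjusted p = 0.0015) and Cyp3a13 (-1.14 ± 0.26, adjusted p = 0.0032) fell.

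The other 6 lists with a camera call lost it with an estimated correlation. Arginine and proline synthesis, enteroendocrine cell and tuft cell genes rose, 3 of 6, 9 of 18 and 3 of 10 (4, 10 and 4 adjusted over the list alone, camera adjusted p from 6.3e-06 to 0.0051, from 0.13 to 0.39 with an estimated correlation). Enteric neuron and glia, dissociation and stress response, and MHC class I genes fell, 2 of 8, 3 of 11 and 2 of 10 (5, 4 and 2 adjusted over the list alone, camera adjusted p from 0.0062 to 0.023, from 0.18 to 0.4 with an estimated correlation). The remaining 11 lists had camera adjusted p from 0.097 to 0.98, and in the fatty acid oxidation, MHC class II and glucocorticoid lists the median, mean and test differed in sign. The largest rises also included Reg3a, an antimicrobial lectin gene (4.19 ± 0.32, adjusted p = 7.1e-09). Among the largest falls were those of Mup20 (-4.62 ± 0.44, adjusted p = 1.7e-07), Ly6d (-4.55 ± 0.33, adjusted p = 5.1e-09), Tfec (-4.43 ± 0.17, adjusted p = 8.7e-14) and Lgals1, which encodes galectin-1 (-4.3 ± 0.37, adjusted p = 4e-08).

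With limma, 2080 genes rose and 2690 fell in fetal organoids, 247 and 481 of them by at least 2-fold, and the share that rose was 43.6%, or 65.6% with arrays centred on their median. Without fetal day 3 arrays 2 and 3, 1266 rose and 1811 fell, Lgr5 rose by 1.22 and Defa21 by 1.76, Itgam fell by 0.8, and Chga (0.63, adjusted p = 0.29), Fut2 (-1.37, adjusted p = 0.12), Lyz1 (0.64, adjusted p = 0.17), Dcn (-1.93, adjusted p = 0.14), Try4 (-1.58, adjusted p = 0.067) and the bile acid (adjusted p = 0.07) and acinar (adjusted p = 0.072) lists were not called. With the spread taken from the groups compared alone, 1011 rose and 1491 fell, and Fut2, Prdm1, Lyz1 and Chga were not called.

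Adult organoids at day 30 were likewise compared with day 3. Limma called few genes, 8 higher and 7 lower, against 2581 at an unadjusted p under 0.05. Cyp2r1, which encodes a vitamin D hydroxylase (-1.25 ± 0.15, adjusted p = 0.00052), Mtarc1 (-0.98 ± 0.14, adjusted p = 0.007) and Rps4l (-1.42 ± 0.26, adjusted p = 0.049) fell. Igf2bp3, an RNA-binding protein gene of fetal tissues, rose (1.06 ± 0.19, adjusted p = 0.049). None of the 12 measured panel genes passed, with differences from -0.89 for Treh to 0.91 for Lgr5 and adjusted p from 0.36 to 1. Sis averaged 11.32 ± 0.21 at day 3 and 11.3 ± 0.22 at day 30 (mean ± SD, n = 4). The call of Igf2bp3 ended without adult day 3 replicate 1 or 3 or adult day 30 replicate 1 or 2 (0.89 to 1.11, adjusted p from 0.11 to 0.23). That of Rps4l ended without adult day 3 replicate 1, 3 or 4 or adult day 30 replicate 2 or 4 (-1.45 to -1.14, adjusted p from 0.052 to 0.23), and both ended with centred, again quantile normalized or blocked arrays.

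Among the lists, 13 had a camera adjusted p under 0.05, and all lost it with an estimated correlation (adjusted p from 0.22 to 0.62). Of the oncofetal and imprinted growth list, 1 of 12 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.34 with an estimated correlation), the gene being Igf2bp3. In the other 12, limma called 0 genes over all genes tested. Adjusted over the list alone, 4 genes fell in lipid absorption (camera adjusted p = 3.6e-07, adjusted p = 0.22 with an estimated correlation), 4 fell in MHC class I presentation and 3 rose in the tuft cell list (camera adjusted p = 1.2e-06 and adjusted p = 0.22 with an estimated correlation in both). Camera also had fetal spheroid (median -0.52), proximal small intestine (-0.45), bile acid (-0.38), MHC class II (-0.37), microbe response (-0.3), sugar uptake (-0.22), leukocyte (-0.15) and cell cycle genes (-0.15) lower and enteroendocrine genes (0.15) higher (camera adjusted p from 2.6e-06 to 0.027, 0.22 to 0.62 with an estimated correlation). Suckling enterocyte (camera adjusted p = 0.75), adult enterocyte (adjusted p = 0.11), Paneth cell (adjusted p = 0.3) and stem cell and Wnt target genes (adjusted p = 0.32) were not called.

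The counts moved with 1 array and do not show that few genes changed. Without adult day 30 replicate 3, limma called 114 genes higher and 90 lower, and without adult day 3 replicate 2 it called 15 and 21. Without any other of these 8 arrays it called 0 to 4 higher. Array weights gave 203 higher and 169 lower, and a repeated quantile normalization 0 and 3. With the spread of these groups alone, Cyp2r1 (adjusted p = 0.21) and Mtarc1 (adjusted p = 0.25) were not called.

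The difference between the culture change of fetal and of adult organoids was tested directly, as the interaction of age and day. Sis (4.78 ± 0.47, adjusted p = 1.8e-06), Arg2 (3.7 ± 0.48, adjusted p = 6.2e-05), Treh (3.3 ± 0.42, adjusted p = 6.2e-05) and Lyz1 (1.8 ± 0.46, adjusted p = 0.03) rose more in fetal organoids. Fcgrt fell more in fetal organoids (-1.43 ± 0.37, adjusted p = 0.032). The other 7 panel genes were not called, with differences from -1.06 for Prdm1 to 1.3 for Lgr5 and adjusted p from 0.1 to 0.87. The call of Lyz1 ended without fetal day 3 replicate 2 or 3, fetal day 30 replicate 2 or 4, or replicate 1 or 2 of adult day 3 or adult day 30 (1.52 to 1.8, adjusted p from 0.053 to 0.072). That of Fcgrt ended without fetal day 3 replicate 3 or 4, fetal day 30 replicate 1, 3 or 4, adult day 3 replicate 2 or 4, or adult day 30 replicate 1 or 3 (-1.43 to -1.26, adjusted p from 0.055 to 0.086) and with centred arrays (adjusted p = 0.058).

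The 6 lists that follow kept their call with an estimated correlation. Of the adult enterocyte list, 6 of 11 were higher and 0 lower (8 and 2 adjusted over the list alone, camera adjusted p = 1.1e-11). Of sugar uptake and fructose metabolism, 5 of 9 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 3.7e-13). Slc2a5, a fructose transporter gene, was among them (2.03 ± 0.37, adjusted p = 0.0022). Of the suckling enterocyte list, 4 of 11 were lower and 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 4.9e-08). Of the lysosome and protein endocytosis list, 9 of 16 were lower and 0 higher (10 and 0 adjusted over the list alone, camera adjusted p = 5.1e-14). Dab2 (-2.47 ± 0.31, adjusted p = 5.2e-05) and the sialidase gene Neu1 (-1.49 ± 0.22, adjusted p = 0.00029) were lower. Of the stem cell and Wnt target list, 7 of 16 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 6.6e-11). Smoc2 (2.16 ± 0.4, adjusted p = 0.0028) differed most. Of the oncofetal and imprinted growth list, 8 of 12 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 3.7e-13). Grb10 was lowest (-1.99 ± 0.19, adjusted p = 1e-06).

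Of the Paneth cell list, 4 of 11 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 7.4e-07, adjusted p = 0.18 with an estimated correlation), led by Defa21 (2.62 ± 0.63, adjusted p = 0.021; 2.49, adjusted p = 0.053 without adult day 30 replicate 1). Of mesenchyme and smooth muscle, 4 of 14 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.081 with an estimated correlation). Acta2 (-1.6 ± 0.27, adjusted p = 0.00091) led the list. By camera the difference was also positive for bile acid and xenobiotic handling, arginine and proline synthesis, enteroendocrine cell and cell cycle genes, with limma calling 5 of 24, 1 of 6, 1 of 18 and 0 of 20 (5, 2, 1 and 0 adjusted over the list alone, camera adjusted p from 5.2e-05 to 0.025, from 0.23 to 0.59 with an estimated correlation). The median of the cell cycle list was 0.07 in fetal and -0.15 in adult organoids. For endothelium, fetal spheroid, enteric neuron and pancreatic acinar cell genes it was negative, with limma calling 2 of 9, 1 of 13, 1 of 8 and 0 of 11 (5, 3, 2 and 6 adjusted over the list alone, camera adjusted p from 2.7e-05 to 0.036, from 0.079 to 0.43 with an estimated correlation).

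The largest differences further included Reg3a (4.53 ± 0.45, adjusted p = 1.8e-06) and Cyp3a11 (5.39 ± 0.46, adjusted p = 3e-07) among those higher, and Tfec (-4.5 ± 0.24, adjusted p = 1e-10), Ly6d (-3.88 ± 0.47, adjusted p = 3.5e-05) and Mup20 (-3.79 ± 0.63, adjusted p = 0.00084) among those lower. With limma, 313 genes were higher and 605 lower, 148 and 245 of them by at least 2-fold, and the share higher was 34.1%, or 45% with centred arrays. When fetal day 3 arrays 2 and 3 were left out, 177 were higher and 386 lower, Smoc2 was 1.41, and Lyz1 (1.03, adjusted p = 0.21), Fcgrt (-1.49, adjusted p = 0.088), Defa21 (1.32, adjusted p = 0.072) and the arginine (adjusted p = 0.23), enteric neuron (adjusted p = 0.065) and acinar (adjusted p = 0.68) lists were not called. Without fetal day 3 replicate 4, 483 genes were higher.

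A tissue maturation score set the organoids against the tissue: per array, the mean log2 level of the 798 genes at least 2-fold higher in adult tissue minus that of the 766 genes at least 2-fold higher in P0 tissue. In fetal organoids the score was -0.28 ± 0.12 at day 3 and 0.57 ± 0.1 at day 30 (mean ± SD, n = 4), a rise of 0.85 (exact two-sided permutation p = 0.0286, the smallest of 70 assignments, adjusted p = 0.0381). The larger part was a fall of the genes high in P0 tissue (mean -0.58), against a rise of those high in adult tissue (mean 0.27). Mesenchyme and endothelium genes fell on the same arrays and are high in P0 tissue. In adult organoids it was 0.88 ± 0.13 and 0.79 ± 0.03, a difference of -0.09 (exact permutation p = 0.229). The changes of fetal and adult organoids differed by 0.94 (exact permutation p = 0.00327 over 4900 assignments within each age). Adult organoids scored 1.16 above fetal organoids at day 3 and 0.22 above them at day 30 (exact permutation p = 0.0286 each, the smallest of 70 assignments, adjusted p = 0.0381). Without fetal day 3 arrays 2 and 3 the rise in fetal organoids was 0.75 and the day 3 difference 1.06, each with an exact permutation p of 0.067, the smallest that 15 assignments allow. Without adult day 3 replicate 2 the adult change was -0.14 (exact permutation p = 0.029).

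**Figure D2:**
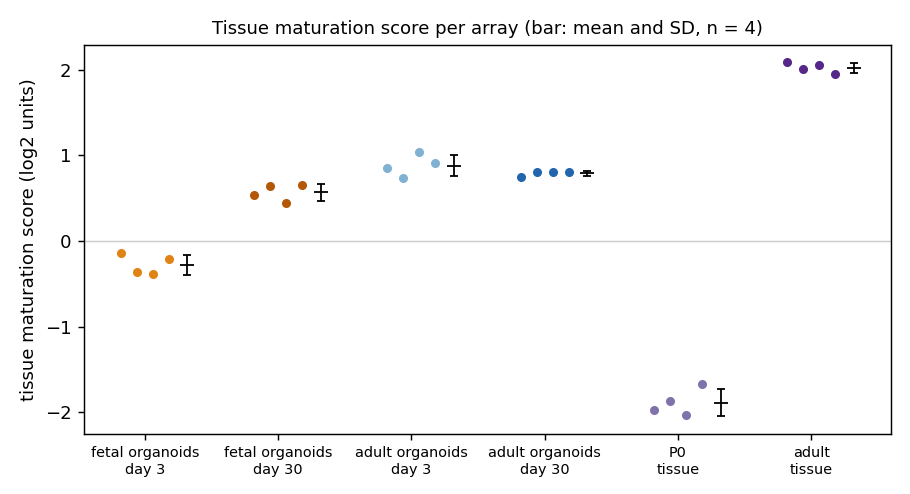
Tissue maturation score in log2 units for each of the 24 arrays, by group, with the mean and SD of each group (n = 4) as a bar beside the points. Fetal organoids moved from a mean of -0.28 at day 3 to 0.57 at day 30, and adult organoids lay at 0.88 and 0.79; the tissues lie at -1.88 and 2.02 because the genes were chosen on them.

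Across genes, fetal culture change and tissue difference had a Pearson r of 0.27 and a Spearman rho of 0.03; genes are not independent replicates, so no p is given. Of the 2243 genes called in both, 70.9% went the same way, with 589 higher in both (312 by chance for independent lists) and 1001 lower in both (327 by chance). Of the 798 genes high in adult tissue, 210 rose and 67 fell in fetal organoids, and of the 766 genes high in P0 tissue, 19 rose and 374 fell. In adult organoids limma called 0 of the 798 and 1 of the 766 (2581 of all genes at an unadjusted p under 0.05). For adult minus fetal organoids at day 3 against tissue, r was 0.33 and rho 0.08, and 71.3% of the 2922 genes called in both went the same way.

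Adult and fetal organoids at day 3 were compared, to see how age of origin shows early in culture. Sis (4.63 ± 0.33, adjusted p = 1.9e-09), Arg2 (4.49 ± 0.34, adjusted p = 3.6e-09) and Treh (3.38 ± 0.3, adjusted p = 4.7e-08) were higher in adult organoids, and Prdm1 (-1.77 ± 0.24, adjusted p = 1.2e-05) and Fcgrt (-1.29 ± 0.26, adjusted p = 0.00074) were lower. Lyz1 (2.48 ± 0.32, adjusted p = 6.7e-06), Lgr5 (1.84 ± 0.39, adjusted p = 0.0013) and Chga (1.33 ± 0.31, adjusted p = 0.0028) were higher. Nox4 was called lower (-0.44 ± 0.15, adjusted p = 0.039), with both means, 2.81 and 3.25, below the negative control medians. Mmp7 (0.84 ± 0.36, adjusted p = 0.1), Mki67 (0.34 ± 0.21, adjusted p = 0.28) and Lct (-0.75 ± 0.39, adjusted p = 0.18) were not called. Uty, a Y-linked gene chosen after its values were seen, was 4.31 to 5.25 on all fetal organoid arrays. It was 3.54 to 3.69 on all adult ones.

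Of the adult enterocyte list, 6 of 11 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.058 with an estimated correlation). Fut2 (-2.31 ± 0.45, adjusted p = 0.00053) and the meprin gene Mep1a (-1.65 ± 0.27, adjusted p = 8.1e-05) were lower. Among suckling enterocyte genes, 7 of 11 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.058 with an estimated correlation). The cubilin gene Cubn was among them (-3.69 ± 0.28, adjusted p = 5.1e-09). Of the lysosome and protein endocytosis list, 13 of 16 were lower and 0 higher (15 and 0 adjusted over the list alone, camera adjusted p = 6.9e-12). Of the Paneth cell list, 7 of 11 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 3.1e-05, adjusted p = 0.29 with an estimated correlation). Defa21 (2.77 ± 0.45, adjusted p = 8e-05) led the list. Of the stem cell and Wnt target list, 11 of 16 were higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.11 with an estimated correlation), with Olfm4 (1.84 ± 0.26, adjusted p = 1.8e-05) beside Lgr5. Of the oncofetal and imprinted growth list, 9 of 12 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 1.8e-12). Igf2bp3 was lowest (-3.09 ± 0.19, adjusted p = 2.4e-10). Of sugar uptake and fructose metabolism, 8 of 9 were higher and 0 lower (8 and 1 adjusted over the list alone, camera adjusted p = 8.9e-08, adjusted p = 0.11 with an estimated correlation). Fbp1 (3.49 ± 0.29, adjusted p = 2.1e-08) differed most.

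Of mesenchyme and smooth muscle, 9 of 14 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.14 with an estimated correlation). Lum was among them (-1.75 ± 0.4, adjusted p = 0.0023). Of the pancreatic acinar cell list, 7 of 11 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.0065, adjusted p = 0.57 with an estimated correlation). Prss2 (-2.83 ± 0.64, adjusted p = 0.0021) differed most, with Clps higher (1.44 ± 0.21, adjusted p = 2e-05). All 8 stomach genes chosen after the values were seen were lower (median -3.64), and of 19 others 6 were lower and 2 higher (median -0.17); without fetal day 3 arrays 2 and 3, 4 of the 8 were lower (median -1.74). Of the other lists with a call, enteroendocrine cell, cell cycle and MHC class I were higher, with 10 of 18, 3 of 20 and 4 of 10 (11, 3 and 4 adjusted over the list alone, camera adjusted p from 0.002 to 0.045, from 0.52 to 0.74 with an estimated correlation). Fetal spheroid, endothelium and enteric neuron were lower, with 9 of 13, 5 of 9 and 3 of 8 (12, 5 and 3 adjusted over the list alone, camera adjusted p from 1.7e-06 to 0.047, from 0.19 to 0.31 with an estimated correlation). The enteroendocrine gene Pyy was lower against its list (-0.88 ± 0.19, adjusted p = 0.0017). The other 15 lists had camera adjusted p from 0.081 to 0.97, and the median, mean and test differed in sign for lipid absorption, microbe response, glucocorticoid, proximal small intestine, leukocyte and erythroid genes.

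The largest differences also included Reg3a (4.91 ± 0.32, adjusted p = 4e-10), higher in adult organoids, and Tfec (-4.82 ± 0.17, adjusted p = 7e-15), Cym, which encodes chymosin (-4.74 ± 0.85, adjusted p = 0.00024), and the stomach genes Gkn2 (-4.38 ± 0.78, adjusted p = 0.00023) and Tff2 (-4.06 ± 0.99, adjusted p = 0.0037), higher in fetal organoids. With limma, 4444 genes were higher and 3099 lower, 539 and 485 of them by at least 2-fold. When fetal day 3 arrays 2 and 3 were left out, 352 were higher by at least 2-fold, Defa21 was 1.47, Cym -2.92 and Gkn2 -1.93, and Lgr5 (0.84, adjusted p = 0.087), Chga (0.99, adjusted p = 0.072), Lum (-1.06, adjusted p = 0.11), Prss2 (-0.97, adjusted p = 0.11), Tff2 (-2.51, adjusted p = 0.13) and the acinar (adjusted p = 0.47), MHC class I (adjusted p = 0.23) and enteric neuron (adjusted p = 0.084) lists were not called. A repeated quantile normalization ended the cell cycle (adjusted p = 0.11), MHC class I (adjusted p = 0.2) and enteric neuron (adjusted p = 0.11) calls.

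**Figure D3:**
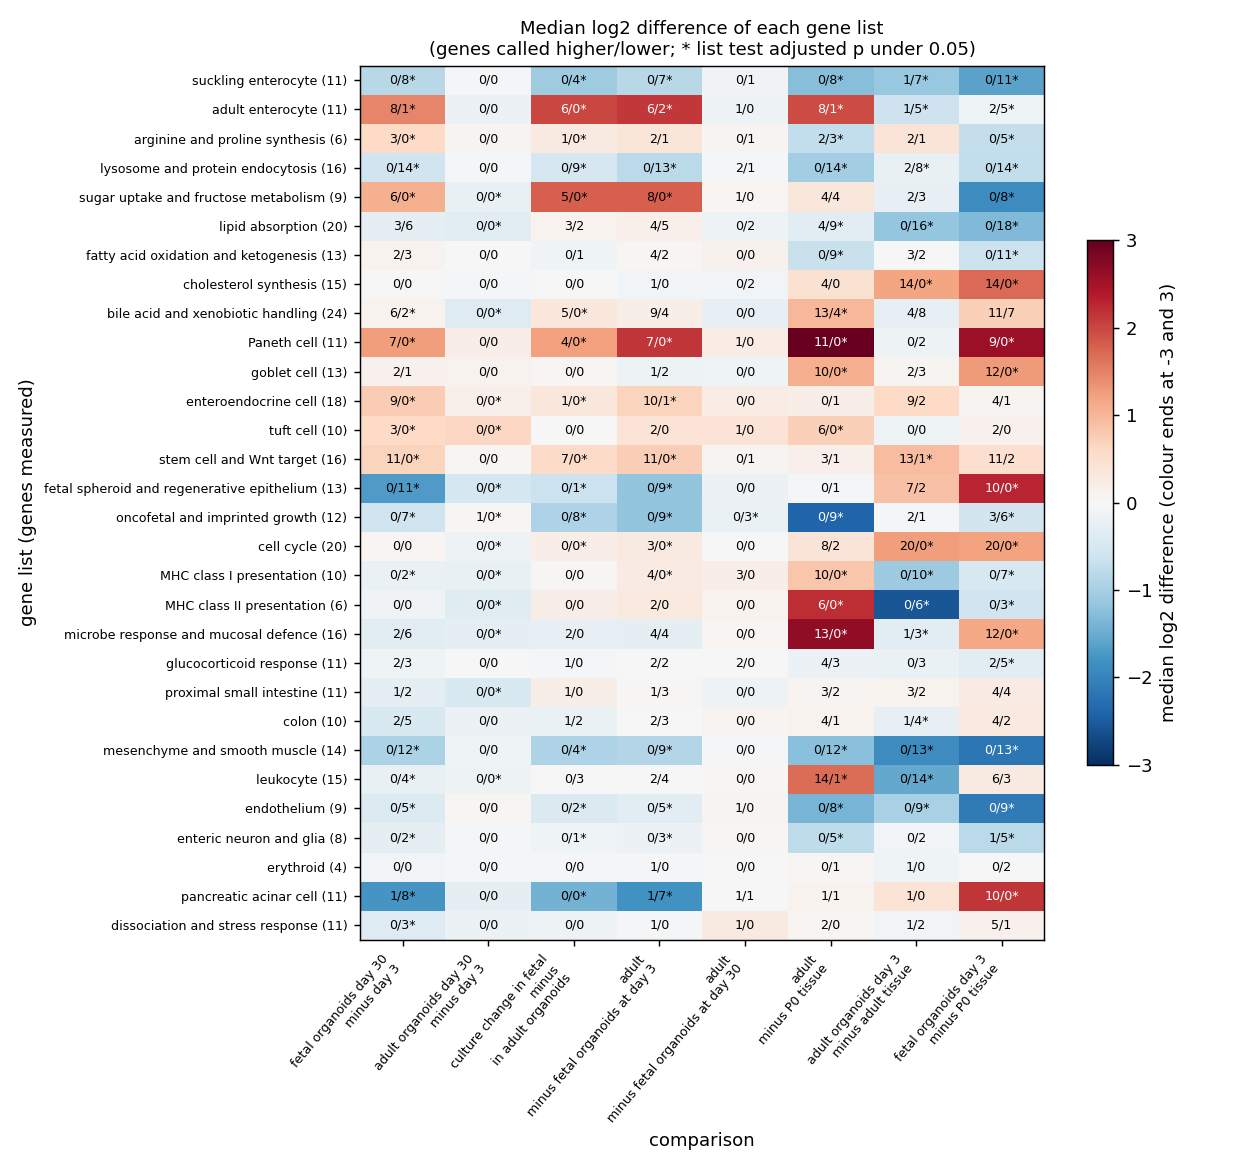
Median log2 difference of the 30 gene lists (vertical, with the number of genes measured) in the 8 comparisons (horizontal), as colour from -3 to 3; each cell gives the genes called higher and lower, and a star marks a camera adjusted p under 0.05 with the preset correlation. The Paneth cell list had a median of 4.57 in the tissue comparison, 1.25 in the culture change of fetal organoids and 0.21 in that of adult organoids.

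At day 30 the same comparison asked what of the difference between adult and fetal organoids was left after culture. None of the 12 measured panel genes passed, with differences from -1.08 for Lct to 0.79 for Arg2 and adjusted p from 0.074 to 0.98. Igf2bp3 (-1.86 ± 0.19, adjusted p = 6.9e-06), Cubn (-2.16 ± 0.28, adjusted p = 6.1e-05), and Gpc3, a glypican gene (-2.33 ± 0.27, adjusted p = 2.1e-05), were still lower in adult organoids. Higher in adult organoids were Ifitm3 (2.72 ± 0.28, adjusted p = 7.1e-06), Ceacam10 (2.22 ± 0.38, adjusted p = 6e-04) and Plbd1 (2.22 ± 0.25, adjusted p = 1.4e-05). Of the oncofetal and imprinted growth list, 3 of 12 were lower and 0 higher (4 and 0 adjusted over the list alone, camera adjusted p = 7.3e-05, adjusted p = 0.061 with an estimated correlation), with Plagl1 next after Igf2bp3 (-1.04 ± 0.14, adjusted p = 8.9e-05).

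Of the suckling enterocyte list, 1 of 11 were lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.056), the gene being Cubn, and of the adult enterocyte list, 1 of 11 were higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.89), the gene being Fbp1 (1.48 ± 0.29, adjusted p = 0.0023). Of the Paneth cell list, 1 of 11 were higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.78), the gene being Pla2g2a (1.92 ± 0.39, adjusted p = 0.0026), and of the stem cell and Wnt target list, 1 of 16 were lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.95). Its gene Tnfrsf19 (-0.33 ± 0.09, adjusted p = 0.024) lost its call without fetal day 30 replicate 2, 3 or 4 or adult day 30 replicate 1, 3 or 4 (-0.34 to -0.25, adjusted p from 0.052 to 0.085). The adult enterocyte, stem cell, arginine, microbe response, cell cycle, colon, leukocyte, enteric neuron and acinar lists had a median, mean and test that differed in sign, and the other 25 lists had camera adjusted p from 0.056 to 0.95.

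Of the 7543 genes called between adult and fetal organoids at day 3, 2028 (26.9%) were called the same way at day 30, 1634 of them higher in adult organoids (302 by chance for independent lists) and 394 lower (67 by chance). With limma, 2088 genes were higher in adult organoids at day 30 and 666 lower, 75 and 40 of them by at least 2-fold. The share higher moved from 75.8% to 52.3% after a repeated quantile normalization (1365 higher and 1246 lower), and with the spread of these groups alone 1228 were higher and 386 lower. Without adult day 30 replicate 1, 369 genes were lower, and without fetal day 30 replicate 3, 417.

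Adult organoids at day 3 were compared with adult tissue, to see what differs between cultured epithelium and whole intestine. Lgr5 (2.62 ± 0.39, adjusted p = 1e-05), Mki67 (1.24 ± 0.21, adjusted p = 4.9e-05) and Chga (0.95 ± 0.31, adjusted p = 0.02) were higher in organoids. Lct (-4.34 ± 0.39, adjusted p = 4.8e-09), Treh (-1.86 ± 0.3, adjusted p = 2.4e-05), Prdm1 (-1.22 ± 0.24, adjusted p = 0.00026) and Fcgrt (-1.18 ± 0.26, adjusted p = 0.00084) were lower. Sis (-0.49 ± 0.33, adjusted p = 0.3), Arg2 (-0.61 ± 0.34, adjusted p = 0.18), Lyz1 (-0.59 ± 0.32, adjusted p = 0.18), Mmp7 (0.81 ± 0.36, adjusted p = 0.093) and Nox4 (-0.15 ± 0.15, adjusted p = 0.53) were not called. The call of Chga ended without adult day 3 replicate 1 or 3 or adult tissue replicate 1 (0.73 to 0.79, adjusted p from 0.075 to 0.089) and after a repeated quantile normalization (0.76, adjusted p = 0.085).

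Genes of other tissue layers and immune cells were lower in organoids. Of the leukocyte list, 14 of 15 were lower and 0 higher (14 and 0 adjusted over the list alone, camera adjusted p = 1.5e-15). Jchain was among them (-5.2 ± 0.2, adjusted p = 9.5e-15). Of mesenchyme and smooth muscle, 13 of 14 were lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 3.2e-11). Acta2 (-3.74 ± 0.19, adjusted p = 5.9e-13) differed most. Endothelium, MHC class I and MHC class II genes were lower, 9 of 9, 10 of 10 and 6 of 6 (9, 10 and 6 adjusted over the list alone, camera adjusted p from 4.5e-11 to 1.7e-08, 0.035 with an estimated correlation). Of the cell cycle list, 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 3.2e-11, adjusted p = 0.2 with an estimated correlation). Of the stem cell and Wnt target list, 13 of 16 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 7.1e-05, adjusted p = 0.17 with an estimated correlation), with Sox9 next after Lgr5 (1.94 ± 0.15, adjusted p = 6.6e-10) and Nkd1 lower (-0.49 ± 0.1, adjusted p = 0.00024). Among suckling enterocyte genes, 7 of 11 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.00025, adjusted p = 0.17 with an estimated correlation). Cubn was lower (-6.37 ± 0.28, adjusted p = 6.3e-14) and Asl higher (0.76 ± 0.09, adjusted p = 3.2e-07). Of the adult enterocyte list, 5 of 11 were lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.0047, adjusted p = 0.17 with an estimated correlation). Xpnpep2 was lowest (-2.91 ± 0.28, adjusted p = 1.9e-08) and Fbp1 higher (1.8 ± 0.29, adjusted p = 2.8e-05). Of the Paneth cell list, 2 of 11 were lower and 0 higher (2 and 0 adjusted over the list alone, camera adjusted p = 0.5).

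Of lipid absorption, 16 of 20 were lower and 0 higher (16 and 0 adjusted over the list alone, camera adjusted p = 2.9e-09, adjusted p = 0.14 with an estimated correlation). Slc27a4 (-2.82 ± 0.18, adjusted p = 2.4e-11) differed most. Of cholesterol synthesis, 14 of 15 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 8.1e-05, adjusted p = 0.42 with an estimated correlation). The other lists with a call, lysosome and protein endocytosis, microbe response, and colon, were lower, 8 of 16, 3 of 16 and 4 of 10 (9, 2 and 4 adjusted over the list alone, camera adjusted p from 0.0059 to 0.027, from 0.089 to 0.34 with an estimated correlation), with 2, 1 and 1 members higher. The remaining 15 lists had camera adjusted p from 0.066 to 0.86. The median, mean and test of goblet cell, proximal small intestine, oncofetal and erythroid genes differed in sign. Xist, transcribed from the inactive X chromosome, was higher in organoids (6.69 ± 1.01, adjusted p = 1e-05). It was 9.81 to 11.58 on all organoid arrays and 3.77 to 4.24 on adult tissue arrays. With limma, 6727 genes were higher in organoids and 4130 lower, 1425 and 1006 of them by at least 2-fold.

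Fetal organoids at day 3 were compared with P0 tissue in the same way. Lct (-3.61 ± 0.39, adjusted p = 1.7e-07), Fcgrt (-3.13 ± 0.26, adjusted p = 3.4e-09), Nox4 (-2.71 ± 0.15, adjusted p = 6.4e-12) and Prdm1 (-0.96 ± 0.24, adjusted p = 0.0029) were lower in organoids. Mmp7 (4.04 ± 0.36, adjusted p = 1.2e-08), Lyz1 (3.21 ± 0.32, adjusted p = 6.5e-08), Sis (1.69 ± 0.33, adjusted p = 0.00032), Lgr5 (1.58 ± 0.39, adjusted p = 0.0027) and Mki67 (1.54 ± 0.21, adjusted p = 5.2e-06) were higher. Arg2 (0.13 ± 0.34, adjusted p = 0.76), Treh (0.08 ± 0.3, adjusted p = 0.84) and Chga (-0.25 ± 0.31, adjusted p = 0.52) were not called.

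Of the suckling enterocyte list, 11 of 11 were lower and 0 higher (11 and 0 adjusted over the list alone, camera adjusted p = 7e-12). Of lipid absorption, 18 of 20 were lower and 0 higher (19 and 0 adjusted over the list alone, camera adjusted p = 3.8e-17). Cd36 (-4.25 ± 0.38, adjusted p = 1.2e-08) differed most. Of mesenchyme and smooth muscle, 13 of 14 were lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 1.5e-16). Acta2 (-4.18 ± 0.19, adjusted p = 1.8e-13) led the list. Of endothelium, 9 of 9 were lower and 0 higher (9 and 0 adjusted over the list alone, camera adjusted p = 1.1e-17). Lysosome and protein endocytosis, sugar uptake and fructose metabolism, fatty acid oxidation, and enteric neuron genes were lower as well, 14 of 16, 8 of 9, 11 of 13 and 5 of 8 (14, 8, 11 and 5 adjusted over the list alone, camera adjusted p from 3.9e-14 to 6.6e-05, from 0.011 to 0.04 with an estimated correlation), with 1 enteric neuron gene higher. Of the adult enterocyte list, 5 of 11 were lower and 2 higher (5 and 3 adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.24 with an estimated correlation), with Fut2 (2.92 ± 0.45, adjusted p = 2.1e-05) and Sis higher. Of the Paneth cell list, 9 of 11 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.18 with an estimated correlation). Itln1 (4.06 ± 0.36, adjusted p = 8.4e-09) differed most. Of the stem cell and Wnt target list, 11 of 16 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.13). Olfm4 was highest (1.6 ± 0.26, adjusted p = 3.9e-05) and Nkd1 lowest (-1.04 ± 0.1, adjusted p = 2e-08). Of the cell cycle list, 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 3.8e-10, adjusted p = 0.18 with an estimated correlation).

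Of the pancreatic acinar cell list, 10 of 11 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.00055, adjusted p = 0.28 with an estimated correlation). Prss2 was among them (3.45 ± 0.64, adjusted p = 0.00018), and all 8 stomach genes chosen after the values were seen were higher (median 4.44), as were 16 of 19 others (median 0.47); without fetal day 3 arrays 2 and 3, 7 of the 8 (median 2.28) and 12 of the 19 were. Microbe response, goblet cell, cholesterol synthesis, and fetal spheroid genes were higher, 12 of 16, 12 of 13, 14 of 15 and 10 of 13 (12, 12, 14 and 10 adjusted over the list alone, camera adjusted p from 8.1e-07 to 0.0019, from 0.18 to 0.28 with an estimated correlation). Arginine synthesis, MHC class I, MHC class II, glucocorticoid and oncofetal genes were lower by test, 5 of 6, 7 of 10, 3 of 6, 5 of 11 and 6 of 12 (5, 7, 3, 5 and 6 adjusted over the list alone, camera adjusted p from 4.6e-06 to 0.0078, from 0.086 to 0.24 with an estimated correlation), though 3 oncofetal genes, with Hmga2 (1.13 ± 0.1, adjusted p = 9.2e-09) among them, and 2 glucocorticoid genes, with Cdkn1a (1.24 ± 0.19, adjusted p = 1.4e-05) among them, were higher. The other 8 lists had camera adjusted p from 0.16 to 0.99, and tuft cell, enteroendocrine, proximal small intestine and leukocyte genes had a positive median and mean with a test below zero.

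**Figure D4:**
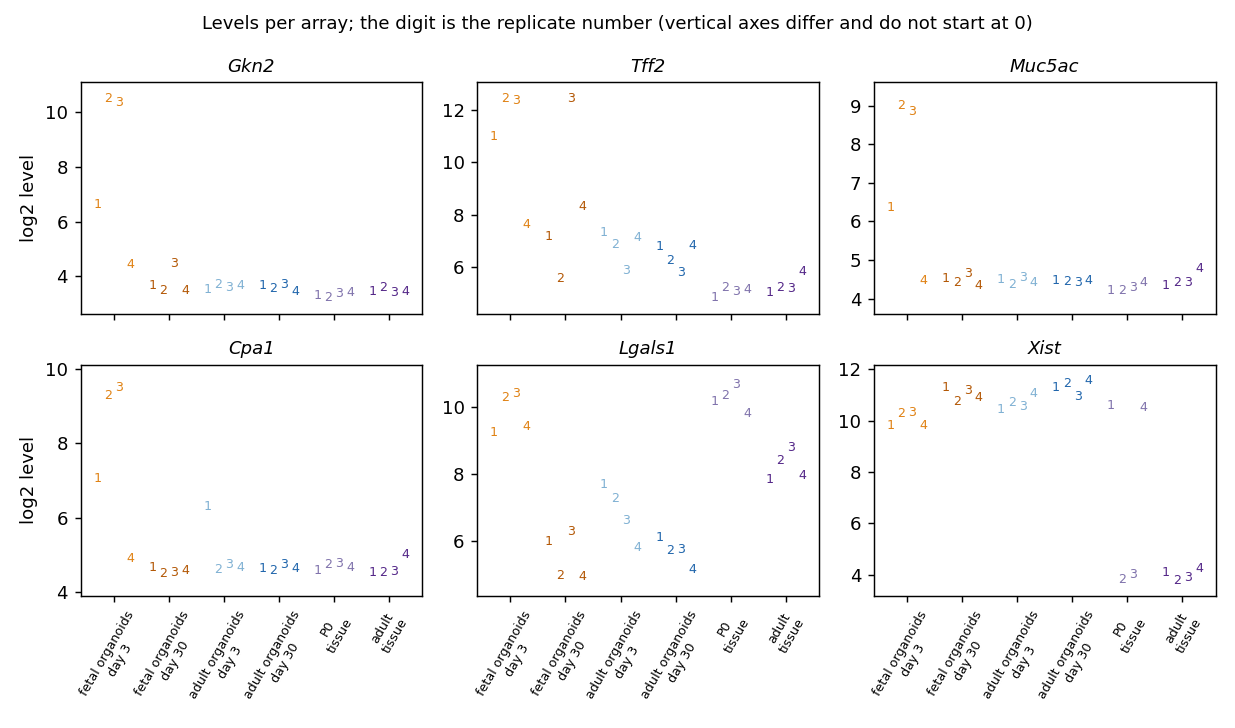
Log2 level of 6 genes on each of the 24 arrays, by group, with the replicate number as the symbol; the vertical axes differ between genes and do not start at 0. Gkn2 lay at 10.5 and 10.38 in replicates 2 and 3 of fetal organoids at day 3 and at 6.63 and 4.45 in replicates 1 and 4.

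Among the largest differences were those of Mup20 (6.17 ± 0.44, adjusted p = 3.3e-10), the stomach gene Tff1 (5.82 ± 0.85, adjusted p = 9.9e-06), Ogn (-4.93 ± 0.44, adjusted p = 1.2e-08) and Adamdec1 (-4.88 ± 0.38, adjusted p = 1.4e-09). With limma, 9378 genes were higher in organoids and 4225 lower, 810 and 992 of them by at least 2-fold. The median difference of all genes was 0.14, and the share higher moved from 68.9% to 54.3% with centred arrays (6101 higher and 5138 lower) and to 53.3% after a repeated quantile normalization (6198 and 5425). Without P0 arrays 2 and 3, 5585 genes were higher. Without fetal day 3 arrays 2 and 3 Sis was 2.62, Lgr5 2.58 and Prss2 1.59, and Prdm1 (-0.74, adjusted p = 0.055) and the adult enterocyte list (adjusted p = 0.18) were not called.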

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

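The tests of pancreas cells, of fetal day 3 arrays 2 and 3, of mesenchymal cells, of Lgals1 and of sex were chosen after the results they bear on were seen. The first pattern is the set of stomach genes high in fetal organoids at day 3, Gkn2 at 6.63, 10.5, 10.38 and 4.45 on the 4 arrays and Muc5ac at 6.36, 9, 8.85 and 4.48. Arrays 2 and 3 are not the whole source of the excess over P0 tissue of the 8 genes chosen for it. Without them these stayed 1.54 to 5.19 higher, 7 called. Of 19 stomach genes not looked at before, 12 (63.2%, against 26.5% of all genes) were then called higher and 0 lower. Their median was 0.42 (all genes 0.171), which decides neither way. Against adult organoids these 8 kept their direction (1.31 to 2.92 higher in fetal organoids), 4 of them called. As the source of the fall to day 30, arrays 2 and 3 stay open. Of the 19 (median -0.23 either way), 7 were called lower at day 30 with all arrays and 2 without these (Muc5ac and Slc5a5). Of the 8, 6 and 4 were, with smaller changes on fewer arrays. Gkn2 went from -4.22 to -1.76, and Tff1 lost its call (-3.85 ± 0.85, then -2.3 ± 0.9, adjusted p = 0.11). Stomach cells in the starting tissue may be the source, but among the 19 the median change was -0.23, with 7 called lower and 1 higher, which decides neither way. Pancreas cells stay open too. All 11 acinar genes had a median change of -1.78, 8 called lower and 1 higher. The 5 abundant ones had -0.49, from -2.05 for Cel to 1.1 for Clps, both genes that other epithelium can express. On adult day 3 replicate 1 Tff1 also reached 8.64, Try4 6.59 and Cpa1 6.29, and on a fetal day 30 array Tff2 12.42. A stomach-like state of fetal intestinal cells was not tested.

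The second pattern is the fall of mesenchyme genes and of Lgals1 between day 3 and day 30 in fetal organoids. Mesenchymal cells in the day 3 cultures stay open as its source. Cells like those of P0 tissue would bring their genes in 1 proportion. Day 3's excess over day 30, as a percent of P0 tissue's, lay within 3 times its median of 12.4% for 7 of 14 genes. It ran from 0.428% for Cnn1 to 178% for Thy1, whose levels lie near background. For Lgals1, at 74.1%, this stays open too. The organoids were grown in ENR medium, no sort or gate that removes such cells is named in the sources used here, and expression by the epithelium itself was not tested.

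The third pattern is a difference in sex-linked genes between the arrays. Xist was 9.81 to 11.58 on all organoid arrays, 10.6 and 10.53 on P0 arrays 1 and 4. It was 3.77 to 4.24 on adult tissue arrays and P0 arrays 2 and 3. The tables argue against sex as the whole source of the tissue difference, since 70.5% of the genes called stayed called in the same direction without P0 arrays 1 and 4. Between adult organoids and adult tissue (Xist 6.69) sex and culture cannot be told apart per gene, as no organoid array lacks Xist signal. Y-linked genes lay between their levels in the other groups on every fetal organoid array (Uty 4.31 to 5.25, Kdm5d 4.61 to 5.12), and lower on adult organoid arrays (Uty 3.54 to 3.69). Sex and age of origin thus cannot be told apart between adult and fetal organoids, where Uty differed by -0.98 at day 3 (adjusted p = 0.16).

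In 6 comparisons no other of the 35 splits called as many genes, the smallest share possible. The genes called, and the most in any other split, were 4770 and 617 for fetal organoids day 30 against day 3. They were 7543 and 315 for adult against fetal organoids at day 3 and 2754 and 1015 at day 30. Adult against P0 tissue gave 8331 and 121. Adult organoids against adult tissue gave 10857 and 47, and fetal organoids against P0 tissue 13603 and 311. For adult organoids day 30 against day 3 chance cannot be excluded, as 2 of 35 splits called as many as the 15 of the real one. The other, which set day 3 replicates 1, 2 and 3 with day 30 replicate 3, called 326 genes. This points to a structure of the samples. For the difference of culture changes, 5 of 100 draws called as many as the real 918, the highest other 2034, so the share alone does not exclude chance. The 4 others all kept the fetal arrays parted by day and so hold the fetal change itself, and the highest draw that did not called 103.

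Some arrays stood apart from the other 3 of their group by Dixon's test, 10 of 96 groups examined, where chance gives about 1 in 20. Adult day 30 replicate 1 had a maturation score of 0.75 (others 0.801 to 0.806). The array median was 4.38 on fetal day 3 replicate 1 (others 4.18 to 4.21), 4.23 on adult day 30 replicate 3 (others 4.28) and 4.31 on P0 replicate 4 (others 4.24 to 4.25). Fetal day 30 replicate 1 had a control area under the curve of 0.88 (others 0.9 to 0.904). Adult tissue replicate 1 was low in Lct at 11.1 (others 11.9 to 12), Treh at 8.86 (others 10.1 to 10.3) and Arg2 at 8.7 (others 10.1 to 10.2). Mmp7 was 10.2 on adult day 30 replicate 3 (others 10.6 to 10.7), and Chga 6.66 on P0 replicate 1 (others 6.97 to 7.02).

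By limma's test the culture change differed between fetal and adult organoids for 918 genes (within the limit of the draws above). Sis was 4.78, Arg2 3.7, Treh 3.3, Lyz1 1.8 and Fcgrt -1.43. The maturation score's change differed by 0.94, but its permutation only tests for no change in either age. Outside the genes compared, 1831 of 33206 transcript clusters without a symbol were called between day 30 and day 3 in fetal organoids, 1403 higher and 428 lower, against 7 in adult organoids.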

How the results depend on the processing

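The tests without fetal day 3 arrays 2 and 3 or without 2 P0 arrays were chosen after seeing the data, and all others before the data were examined. No named gene or list that was called turned its direction under any alternative run. Over all genes called in both fits, 9694 of 9696 kept their direction after a repeated quantile normalization in adult organoids against adult tissue, 13573 of 13575 with the mean of clusters in fetal organoids against P0 tissue, and all did in the other fits counted. Of 501 calls of named genes, 500 were kept with the mean of all clusters of a gene, 494 with a trended and robust prior, 493 with array weights, 485 with a replicate block, 479 with centred arrays, 477 after a repeated quantile normalization and 454 with the compared groups alone. With dim genes left out, 488 of 488 were kept, and leaving out 1 array kept 4122 of 4376. Of 117 list calls, 117 were kept with the mean of clusters and with the trended prior, 116 with the replicate block, 113 with the compared groups alone, 110 with centred arrays, 109 with array weights, 107 after a repeated quantile normalization, 104 with dim genes left out and 38 with an estimated correlation. With fetal day 3 arrays 2 and 3 left out, 248 of 300 genes and 62 of 71 lists kept their call, without P0 arrays 1 and 4, 189 of 200 and 37 of 39, and without P0 arrays 2 and 3, 184 of 200 and 39 of 39. What signal over background limits are genes near the floor, where a fall cannot be seen; the control area under the curve was 0.865 to 0.922, and 16966 of 30702 genes passed the dim filter.

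Counts of called genes moved over 1.5 times as follows, higher before lower. At an adjusted p under 0.01, a stricter threshold by construction, they were 1113 and 1610 in fetal organoids day 30 against day 3, 0 and 3 in adult organoids, 137 and 285 for the difference of culture changes, 2907 and 1899 for adult against fetal organoids at day 3, 1056 and 233 at day 30, 2706 higher in adult against P0 tissue and 5793 higher in fetal organoids against P0 tissue. With the compared groups alone, which leaves fewer arrays to estimate the spread, they were 1011 and 1491 in fetal organoids, 1 and 0 in adult organoids and 1228 and 386 for adult against fetal organoids at day 30. With centred arrays they were 3485 higher in fetal organoids, 2 and 4 in adult organoids and 6101 higher in fetal organoids against P0 tissue. After a repeated quantile normalization they were 0 and 3 in adult organoids, 1365 and 1246 for adult against fetal organoids at day 30 and 6198 higher in fetal organoids against P0 tissue. Array weights gave 203 and 169 in adult organoids and 480 and 921 for the difference of culture changes, and a dim filter, which leaves fewer genes, 5999 higher in fetal organoids against P0 tissue. Leaving out fetal day 3 arrays 2 and 3, thus with fewer arrays, they were 1266 higher in fetal organoids, 177 and 386 for the difference, 92 higher there by at least 2-fold and 352 higher by at least 2-fold for adult against fetal organoids at day 3. Without P0 arrays 2 and 3 they were 2480 higher in adult against P0 tissue and 5585 higher in fetal organoids against P0 tissue. For the centred, normalized and weighted arrays the cause was not tested.

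With a replicate block, which treats arrays of 1 number as related, 0 genes were higher and 3 lower in adult organoids day 30 against day 3, with 0 and 1 by at least 2-fold, and 1959 and 2578 in fetal organoids. The replicate numbers do not pair the arrays: an array correlated best with the array of its own number in 0 to 2 of 4 cases per comparison, with correlations from -0.31 to 0.3.

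In adult organoids day 30 against day 3, genes called by at least 2-fold, 2 higher and 2 lower, became 0 and 1 with centred arrays and after a repeated quantile normalization, 5 and 38 with array weights, 0 and 0 with the compared groups alone and 1 higher with a trended and robust prior. The limma count at an unadjusted p under 0.05 was 2581. Leaving out 1 array gave 0 to 114 genes higher and 3 to 90 lower, and 0 to 12 and 1 to 32 by at least 2-fold, the highest without adult day 30 replicate 3. It gave 219 to 483 higher for the difference of culture changes, the highest without fetal day 3 replicate 4, and 369 to 651 lower for adult against fetal organoids at day 30, the lowest without adult day 30 replicate 1 and 417 without fetal day 30 replicate 3. The adult change of the maturation score ran from -0.14 to -0.04, with an exact permutation p of 0.029 without adult day 3 replicate 2, and the cause was not tested. Without fetal day 3 arrays 2 and 3 the score rose by 0.75 in fetal organoids and differed by 1.06 at day 3, each with an exact permutation p of 0.067, because 15 assignments allow no smaller one.

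Genes and lists that were not called changed sign near 0, and the cause was not tested. With centred arrays these were Sis at 0 in adult organoids day 30 against day 3, Treh at -0.01 in fetal organoids against P0 tissue, and for adult against fetal organoids at day 30 the adult enterocyte list (adjusted p = 0.96) and the stem cell and Wnt target list (adjusted p = 0.96). That list also did so with the mean of clusters (adjusted p = 0.93) and with array weights (adjusted p = 0.87). After a repeated quantile normalization they were Lct at 0 in adult against P0 tissue and Treh at 0 in fetal organoids against P0 tissue. With array weights they were Mki67 at -0.01 in fetal organoids day 30 against day 3, Chga at 0.02 in adult organoids, Treh at -0.06 and Mki67 at 0 for adult against fetal organoids at day 30, and Lct at 0.08 in adult against P0 tissue. Without fetal day 3 arrays 2 and 3 they were Mmp7 at -0.01 and Lct at -0.21 in fetal organoids, Mmp7 at -0.26 and Lct at -0.11 for the difference of culture changes, and Chga at 0.09 in fetal organoids against P0 tissue. Without P0 arrays 1 and 4 Lct was 0.05 in tissue, and without P0 arrays 2 and 3 Treh was -0.13 in fetal organoids against P0 tissue.

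Leaving out 1 array also turned the sign of genes that were not called, whose values over all arrays left out in turn were as follows. In fetal organoids day 30 against day 3 Lct ran from -0.04 to 0.56 and Mki67 from -0.02 to 0.33. In adult organoids Sis ran from -0.12 to 0.09, Chga from -0.25 to 0.16 and Lct from -0.3 to 0.28, and for the difference of culture changes Lct from -0.03 to 0.66. For adult against fetal organoids at day 30 Fcgrt ran from 0 to 0.47, Treh from -0.11 to 0.37, Mki67 from -0.15 to 0.14 and Nox4 from -0.05 to 0.02. In adult against P0 tissue Lct ran from -0.1 to 0.19, and in fetal organoids against P0 tissue Arg2 from -0.02 to 0.31 and Treh from -0.02 to 0.19. The cause was not tested.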

Other observations

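The genes in the next 2 paragraphs were chosen after their values were seen, and no test beyond those of the report was run on them. Some differences between adult and fetal organoids were called the same way at day 3, at day 30 and between adult and P0 tissue: 251 genes were higher on the adult side in all 3 comparisons (245 by chance for independent lists), which is no excess, and 148 on the fetal or newborn side (48 by chance). On the fetal side were Gpc3, a glypican gene (-3.86 at day 3, -2.33 at day 30 and -4.47 in tissue, log2), Igf2bp3, an RNA-binding protein gene (-3.09, -1.86 and -3.16), and Hif3a, of the response to low oxygen (-1.74, -1.31 and -2.6).

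On the adult side were Oit1 (1.34 at day 3, 2.1 at day 30 and 4.39 in tissue, log2), Pla2g2a, a phospholipase gene of Paneth cells (2.17, 1.92 and 3.05), and Rgs13, a gene of tuft cells (2.6, 1.9 and 2.02). Across genes, adult minus fetal differences at day 3 and day 30 had a Pearson r of 0.58 and a Spearman rho of 0.54, and of the 2041 genes called at both days 99.4% went the same way. Against the tissue difference, the day 30 difference had an r of 0.08, and 53.6% of 967 genes called in both went the same way, 336 higher in both (313 by chance) and 182 lower in both (81 by chance). Of the 798 genes high in adult tissue, 66 were higher and 7 lower in adult than in fetal organoids at day 30, and of the 766 genes high in P0 tissue 16 and 64.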
